A study of Arabidopsis thaliana with 3 samples.

How the data were processed

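Poly(A) RNA was sequenced from 3 seedling samples of 1 group, numbered as replicates 1, 2 and 3 in the labels. Per the labels' protocols, total RNA was treated with DNase and poly(A) RNA was isolated on oligo(dT) beads. The authors deposited, per the file headers, a whole-number count for each gene and the length of each gene in bases. The submitters' processing notes name the genome build TAIR 10. The aligner, the counting tool, the annotation version and the strand setting are not given in the sources used here. The deposited counts were not normalized, since they are whole numbers with a different sum in each library, and each file holds 1 replicate. The files list the same 27655 genes with the same lengths.

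Gene IDs were looked up in the RefSeq annotation of the assembly TAIR10.1, which was used only for names, biotypes, GC content and overlaps between genes. Of the IDs, 27445 matched (27444 protein-coding genes and 1 pseudogene). The other 210 are plastid and mitochondrial IDs, which are printed as the files give them. Of the nuclear gene lengths, 27270 (99.4%) equal the exon union of the RefSeq gene. The files give no coordinates, and because the builds differ in name none from the reference are printed. By the reference 6757 genes (24.4%) overlap another gene of the files, and for 5890 of them the partner with the longest overlap is on the opposite strand.

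Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.01, 0.991 and 0.997. CPM is the count divided by the effective library size and multiplied by 1000000. TPM is the count divided by that size and by the deposited gene length in kb, scaled to sum to 1000000 in each library. One CPM equals 20.8, 18.5 and 24.1 counts in replicates 1, 2 and 3, and the floor that a count of 0 allows was set at 3 counts. A gene was called detected at 1 CPM or more in all 3 libraries.

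The spread between replicates was estimated in edgeR with an intercept-only design over detected genes. A gene was called more variable than the trend when the deviance of its negative binomial fit at the trended dispersion exceeded chi-square with 2 degrees of freedom, at a Benjamini-Hochberg adjusted p under 0.05. For the level of a list, the median of log2(TPM + 0.1) of its members was set against 10000 random lists of the same size from all nuclear protein-coding genes. A list outside the central 95% was called, with a two-sided permutation p adjusted over the 21 lists. For the spread of a list, the median log2 ratio of gene dispersion to trend was set against 10000 random lists matched in 20 bins of mean CPM, for lists with 5 or more detected members. Differences between genes were tested in limma 3.58.1 on log2 ratios within each library with 0.5 counts added, moderated over all detected genes.

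The 21 lists hold 295 genes and were fixed, with the tests and the rule for named genes, before the data were examined. They cover coenzyme A synthesis, Nudix hydrolases, decapping and decay, cap binding, NAD synthesis, nuclear photosystem genes, the Calvin cycle, cytosolic ribosomal proteins, reference genes, the clock, heat shock, touch and wounding, defence, cold and drought, cell division, and markers of root, epidermis, shoot meristem, flower, seed and pollen. The symbol or product of every ID was checked in RefSeq and no gene left its list. RefSeq gives the name RPS13A to AT4G00100, which the list names RPS13B. The genes named in the text were the 10 nuclear and 3 organelle genes highest in CPM, all genes of coenzyme A synthesis, NUDT11, the 4 highest Nudix genes and those below 1 CPM in all libraries. They were also the 2 highest and the lowest member of each other list, the 10 variable genes with the smallest p at 10 CPM or more, and the 3 most variable members of a list called for its spread. NUDT16, NUDT10, NUDT21, NUDT6, PSBY and the genes named only in the closing section were chosen after their values were seen.

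The test of variable genes, the list tests and the ratio to a reference gene were tried on simulated data. Genes were simulated with dispersions of the trend, apart from a list made more variable, so other differences in dispersion between real genes were not covered. The tests and corrections added after seeing the data, other than the separate spread, were not simulated. The changed genes, the reference genes and the genes counted for the ratios were limited to 11518 genes at 10 CPM or more. Recovery and ratio errors below that level, as for COAD at 9.57 CPM and the lower Nudix genes, were not simulated. With 200 of 18181 genes changed in simulated libraries of the same depth, the test of variable genes recovered 85% of those changed 1.5-fold and 100% of those changed 2-fold, with 7 false calls. The coefficient of variation at the median of the trend was overestimated there, at 6.38% against 4.92% simulated. With no gene changed the test made 0 calls among 18138 genes (5.29% at an unadjusted p under 0.05), and that coefficient was estimated at 4.69%. Of 200 simulated lists of 15 genes with no effect, 4% had a level p and 1.5% a spread p under 0.05. The ratio to a reference gene gave on average 3.43% false calls over 40 simulated reference genes, and up to 30.7% for a single reference, whose error all its ratios share. With a separate spread for each gene, chosen after seeing the data, it gave 4.48% on average and up to 45.8%. A single reference gene such as NUDT11 or COAE is therefore subject to that shared error.

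The alternatives were DESeq2 1.42.0 size factors and dispersion outliers, total counts, other filters, pseudocounts and moderation, CPM in place of TPM, the mean in place of the median, and leaving out each replicate in turn. Alternatives added after seeing the data were a separate spread for each gene of a ratio, removal of each library's trend with gene length or GC content, removal of the median change of the plastid genes in each library, and leaving out genes that overlap another. Other libraries of the study were not analysed here.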

Results

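Poly(A) RNA was sequenced from seedlings of the Arabidopsis thaliana accession Col-0 collected 12 days after germination. The series concerns RNA that carries dephospho-CoA, an intermediate of coenzyme A synthesis, at its start, and its title names the Nudix hydrolase NUDT11. The libraries analysed here were ordinary RNA-seq of 1 group with 3 replicates, so no comparison between conditions was possible. The comparisons were between genes, between gene lists and between replicates. Gene counts summed to 20520418, 18622323 and 24181634 in replicates 1, 2 and 3. Values with ± are means and SDs over the 3 libraries (n = 3). The labels do not say that the replicates were separate cultures. The edgeR and limma p-values therefore measure only the spread between these samples, which may be technical. Permutation and Fisher's exact p-values set genes against genes and do not measure that spread.

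The most abundant transcripts of the seedlings were those of photosynthesis. The most abundant nuclear transcript was LHCB1.3 (AT1G29930), an antenna protein of photosystem II, at 24179.7 ± 1072 CPM (counts per 1000000, SD, n = 3). RBCS1A (AT1G67090), a small subunit of Rubisco, followed at 14433 ± 481 CPM, and LHCB1.5 (AT2G34420), another photosystem II antenna protein, at 13207 ± 969 CPM. Rubisco activase RCA (AT2G39730) stood at 11083 ± 103 CPM and LHCB1.1 (AT1G29920) at 10987 ± 207 CPM. The rest of the 10 highest were all antenna genes. LHCA4 (AT3G47470) was at 8293 ± 141 CPM, LHCB1.2 (AT1G29910) at 7796 ± 307 CPM and LHCB3 (AT5G54270) at 7375 ± 289 CPM. LHCB5 (AT4G10340) was at 7261 ± 154 CPM and LHCA1 (AT3G54890) at 5918 ± 71.9 CPM. LHCB1.1, LHCB1.2 and LHCB1.3 are near-identical copies, so the split of reads between them is uncertain.

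Nuclear genes held 99.1 ± 0.0492% of the counts and plastid genes 0.867 ± 0.0489% (SD, n = 3). The plastid share was 0.811% in replicate 1 (95% exact Clopper-Pearson interval 0.807% to 0.815%), 0.901% in replicate 2 (0.897% to 0.905%) and 0.889% in replicate 3 (0.885% to 0.892%). Mitochondrial genes held 0.00601 ± 0.000277%. Intervals and floors cover counting error only. The highest plastid gene, ATCG00480, was at 3182 ± 109 CPM, ATCG00470 at 2098 ± 162 CPM and ATCG00220 at 796 ± 150 CPM. A level of 1 CPM or more in all 3 libraries was reached by 18101 of 27655 genes (65.5%), among them 74 plastid and 8 mitochondrial genes. No count in any library was found for 4163 genes. A count of 0 allows a level of up to 0.144 CPM in replicate 1, 0.163 CPM in replicate 2 and 0.124 CPM in replicate 3.

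Among the gene lists fixed before the data were examined, those of photosynthesis and protein synthesis were the highest. Nuclear photosystem genes had a median of 3747 TPM (length-corrected level, scaled to 1000000 per library), with 41 of 41 members detected. They took 16.3%, 17.0% and 16.8% of the counts of replicates 1, 2 and 3 (16.7 ± 0.337%). Calvin cycle genes had a median of 1159 TPM and took 5.39 ± 0.056% of counts. Cytosolic ribosomal proteins had a median of 267 TPM (0.759 ± 0.0135% of counts) and the genes often used as references a median of 201 TPM (0.84 ± 0.0148%). All nuclear protein-coding genes had a median of 5.12 TPM. Each of these 4 lists lay above all 10000 random lists of its size, at the smallest p these permutations can give (two-sided, 0.00020, Benjamini-Hochberg adjusted 0.00105). The percentile describes these libraries, since genes are not replicates.

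Within the photosystem list LHCB1.3 and LHCB1.5 were the highest, and LHCB4.3 (AT2G40100) was the lowest at 12.3 ± 1.33 TPM. In the Calvin cycle list, RBCS1A reached 16586 ± 220 TPM and RCA 7690.4 ± 194 TPM, while the lowest member, the triose-phosphate isomerase TPI (AT2G21170), was still at 368 ± 6.61 TPM. RPL3A (AT1G43170) at 679 ± 18.0 TPM and RPL10A (AT1G14320) at 668 ± 14.1 TPM led the ribosomal proteins, and RPP0A (AT2G40010) was lowest at 11.7 ± 1.104 TPM. The polyubiquitin gene UBQ10 (AT4G05320) was at 1274 ± 35.3 TPM, the glycolytic GAPC2 (AT1G13440) at 1152.5 ± 24.9 TPM and SAND (AT2G28390) at 18.8 ± 0.896 TPM. Of the photosystem genes 17 of 41 overlap another gene in the reference, whose reads cannot be told apart if strand was ignored in counting.

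**Figure D1:**
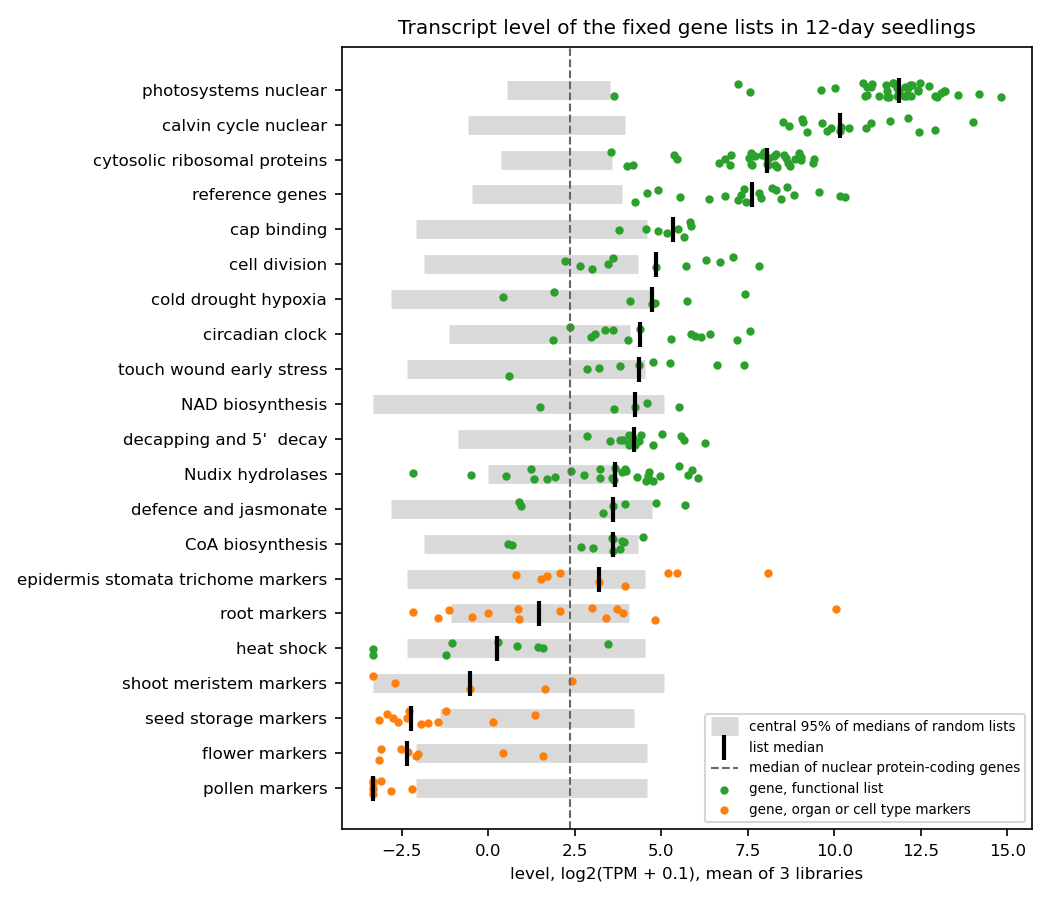
Levels of the members of the 21 gene lists, as log2(TPM + 0.1) averaged over the 3 libraries, 1 point per gene, with the list median as a black bar and the central 95% of medians of 10000 random lists of the same size in grey. The medians of the photosystem list (3747 TPM) and the Calvin cycle list (1159 TPM) lie far to the right of the grey bands, and those of the pollen, flower and seed storage markers to the left.

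Genes that make coenzyme A were all transcribed at modest levels in these seedlings. The pantothenate kinase PANK2 (AT4G32180) was the highest at 21.9 ± 1.11 TPM (SD, n = 3). COAD (AT2G18250), which makes dephospho-CoA, was at 15.004 ± 3.13 TPM, and COAE (AT2G27490), the kinase that converts dephospho-CoA to CoA, at 12.1 ± 1.44 TPM. The pantothenate synthetase PTS (AT5G48840) was at 14.5 ± 1.45 TPM, COAB (AT1G12350) at 13.9 ± 0.587 TPM, PANK1 (AT1G60440) at 12.1 ± 0.347 TPM and HAL3A (AT3G18030) at 11.9 ± 0.175 TPM. KPHMT2 (AT3G61530) was at 8.13 ± 0.19 TPM and KPHMT1 (AT2G46110) at 6.38 ± 0.422 TPM. The second copies HAL3B (AT1G48605) and COAB2 (AT5G02080) were lowest, at 1.51 ± 0.577 and 1.397 ± 0.0726 TPM. The list median of 12.1 TPM lay at percentile 87.1 of random lists, inside the central 95% (permutation p 0.257, adjusted 0.338). Of the 11 members, 10 were detected in all libraries, all but HAL3B, and 5 overlap another gene.

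The balance of the enzyme that makes dephospho-CoA and the one that uses it was compared within each library. COAD exceeded COAE by 0.29 on the log2 scale (SE 0.13, limma p 0.0269), and was higher in 3 of 3 libraries, by 0.50, 0.22 and 0.15. The p was 0.0485 adjusted over the list alone and 0.031 adjusted over all 18100 genes tested. The difference rested on replicate 1 and on the correction for gene length. Without replicate 1 it was 0.19 (limma p 0.344), and as CPM without length correction COAD lay below COAE by −0.34 (limma p 0.0105). The difference was drawn from 598 counts of COAD and 752 of COAE over the 3 libraries. The moderated fit had 36200 degrees of freedom and the same SE for every gene tested of the list. Its p thus treats as known a spread pooled over all genes tested. It does not rest on the spread of COAD minus COAE itself in the 3 libraries.

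NUDT11 (AT5G45940), the hydrolase named in the title, was among the higher members of its family, at 27.2 ± 0.528 TPM (SD, n = 3; 17.29, 17.39 and 17.71 CPM). Of the 24 other Nudix genes tested, 5 were higher than NUDT11 and 19 lower (limma, adjusted over the list alone, and the same 5 and 19 over all 18100 genes tested). NUDT27 (AT5G06340) was the highest at 66.6 ± 10.2 TPM, above NUDT11 by 1.28 on the log2 scale (SE 0.08, limma adjusted p 3.17e-05). NUDT17 (AT2G01670) was at 59.4 ± 3.60 TPM, above it by 1.12, and NUDT19 (AT5G20070) at 54.7 ± 2.05 TPM, above it by 1.00. NUDT26 (AT3G10620) was at 45.2 ± 3.68 TPM, above it by 0.73, and NUDT16 (AT3G12600) at 31.3 ± 1.84 TPM, above it by 0.20. Each of these 5 had a limma adjusted p of 0.00906 or less. The limma p of NUDT16 was 0.0083, and 0.00899 adjusted over all 18100 genes tested. Adjustment changed it so little because nearly all genes tested were called, so being called is not particular to the family.

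The Nudix genes below NUDT11 ranged from NUDT21 (AT1G73540) at −0.14 (SE 0.05, limma adjusted p 0.0308, not called without any 1 of the replicates) to NUDT6 (AT2G04450) at −4.32 (SE 0.05, limma adjusted p 9.82e-08). With only 25, 23 and 33 counts of NUDT6, that SE rests on close agreement of 3 values and may be too small. It was 0.13 with a separate spread for each gene. NUDT24 (AT5G19470) had 5, 1 and 2 counts, a mean of 0.122 ± 0.1 TPM, and NUDT10 (AT4G25434) was at 0.611 ± 0.164 TPM. Neither passed the filter of 1 CPM, so neither was tested. The family median of 12.5 TPM lay at percentile 96.6 of random lists (permutation p 0.0674, adjusted 0.109), and 25 of 27 members were detected. Without replicate 2 it lay at 97.7 (permutation adjusted p 0.08205) and by the mean at 99.3 (0.0245), both outside the central 95%, and over detected genes alone at 69.3 (0.722). As CPM, without length correction, 8 Nudix genes were called higher and 11 lower. The error of NUDT11 is shared by every ratio, and NUDT11 overlaps AT5G45930 (111 CPM) on the opposite strand by 136 bases, whose reads cannot be told apart from its own if strand was ignored in counting. In all, 8 of the 27 Nudix genes overlap another gene. NUDT26 is among them, with 225 bases shared with AT3G10630 (21.7 CPM) on the opposite strand.

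**Figure D2:**
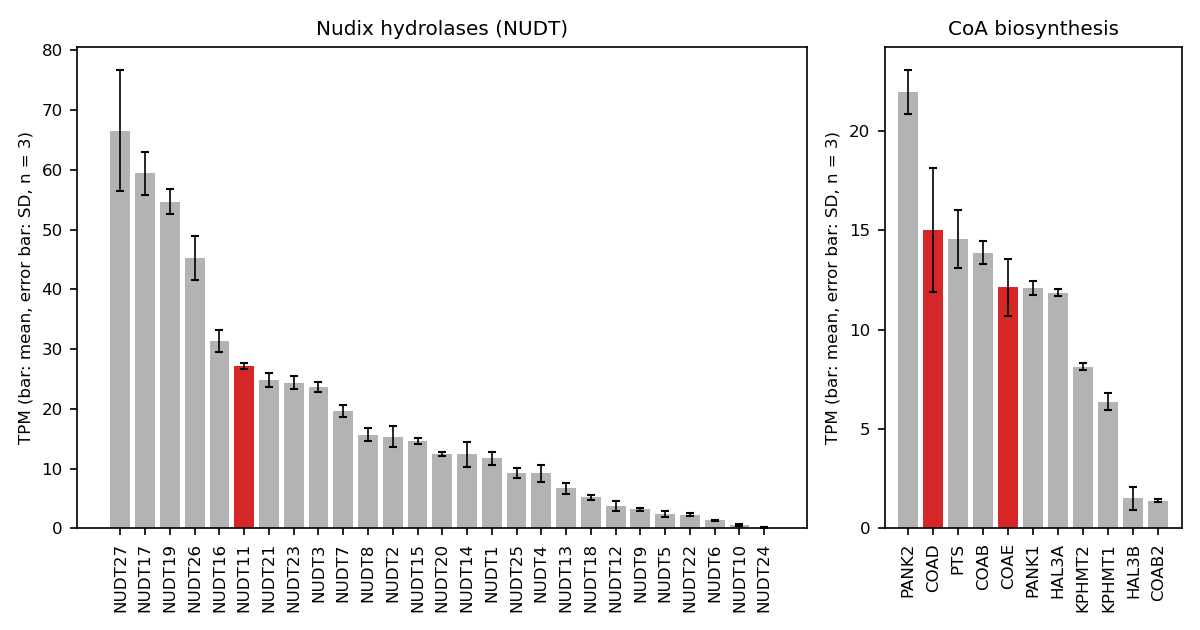
Level of each Nudix hydrolase gene (left) and each gene of coenzyme A synthesis (right) in TPM, as bars of the mean over the 3 libraries with the SD as error bar. NUDT11 (27.2 TPM), COAD (15.004 TPM) and COAE (12.1 TPM) are drawn in red, and NUDT27, NUDT17, NUDT19, NUDT26 and NUDT16 stand above NUDT11.

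The cap-binding list and the decapping and decay list lay high among random lists, and over detected genes alone neither list passed adjustment. The cap-binding list had a median of 40.3 TPM, percentile 99.7 of random lists (permutation p 0.0072, adjusted 0.0252), and over detected genes alone it lay at 98.1 (permutation adjusted p 0.128). Its highest members were the translation initiation factors EIFISO4G1 (AT5G57870) at 57.8 ± 1.91 TPM and NCBP (AT5G18110) at 56.4 ± 0.843 TPM, and its lowest was EIFISO4G2 (AT2G24050) at 13.5 ± 1.08 TPM. The decapping and decay list had a median of 18.6 TPM, percentile 98.7, outside the central 95% (permutation p 0.0262, adjusted 0.055). Over detected genes alone it lay at 85.3, inside the central 95% (permutation adjusted p 0.453). Other settings gave a permutation adjusted p of 0.0018 by the mean, 0.0119 by CPM and 0.042 to 0.063 with a replicate or overlapping genes left out. DCP5 (AT1G26110), a decapping cofactor, was at 76.1 ± 2.26 TPM, the helicase RH6 (AT2G45810) at 50.8 ± 4.88 TPM and the scaffold-related VCR (AT3G13290) at 7.11 ± 0.363 TPM. The 5 genes of NAD synthesis had a median of 18.7 TPM, percentile 89.5 (permutation p 0.211, adjusted 0.295). They ran from QPT (AT2G01350) at 45.5 ± 1.11 TPM and NADS (AT1G55090) at 23.8 ± 0.678 TPM down to NMNAT (AT5G55810) at 2.73 ± 0.0887 TPM.

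Markers of pollen, seed and flower were the lowest of the lists. None of the 8 pollen markers was detected and 5 had no count in any library. Their median was 0 TPM, percentile 0.175 of random lists (permutation p 0.0072, adjusted 0.0252). HAP2 (AT4G11720) had 12 counts in all, MYB101 (AT2G32460) had 4 and MGH3 (AT1G19890) had 0. Of the 12 seed storage markers, 1 was detected, the oleosin OLEO4 (AT3G27660) at 2.46 ± 0.243 TPM. EM6 (AT2G40170) was at 0.994 ± 0.746 TPM and the cruciferin CRB (AT1G03880) had 1 count. Their median was 0.131 TPM, percentile 0.94 (permutation p 0.019, adjusted 0.0443), and percentile 3.76, inside the central 95%, when genes overlapping another were left out. Flower markers had a median of 0.118 TPM, percentile 1.9, and their p did not pass adjustment (permutation p 0.0382, adjusted 0.0729). Without replicate 2 they lay at percentile 2.53, inside the central 95%, and by the mean at 0.11 (permutation adjusted p 0.00504). The floral genes SEP3 (AT1G24260) at 2.90 ± 0.316 TPM and PI (AT5G20240) at 1.26 ± 0.0555 TPM were detected, and AP1 (AT1G69120) had 1 count.

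The lists of root, epidermis and shoot meristem markers lay inside the central 95% of random lists. BGLU23 (AT3G09260), a root beta-glucosidase, was at 1055 ± 41.3 TPM and the iron transporter IRT1 (AT4G19690) at 28.0 ± 0.954 TPM, while PLT1 (AT3G20840) had 13 counts. The root list had a median of 2.94 TPM, percentile 25.5, with 10 of 14 members detected (permutation p 0.511, adjusted 0.525). Epidermal PDF1 (AT2G42840) was at 272 ± 13.6 TPM, ATML1 (AT4G21750) at 44.0 ± 1.249 TPM and the trichome regulator GL1 (AT3G27920) at 1.65 ± 0.34 TPM. With 8 of 9 members detected, their list had a median of 9.20 TPM, percentile 73.8 (permutation p 0.525, adjusted 0.525). The meristem genes KNAT1 (AT4G08150) and STM (AT1G62360) were at 5.22 ± 0.547 and 3.004 ± 0.355 TPM, and WUS (AT2G17950) had no count in any library. With 2 of 5 members detected, the median of the meristem list was 0.602 TPM, percentile 15.2 (permutation p 0.304, adjusted 0.354).

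Cell division and clock genes were also above the typical gene. Cell division genes had a median of 29.0 TPM, percentile 99.5 (permutation p 0.011, adjusted 0.033), led by the replication-dependent histones H3.1e (AT5G65360) at 228 ± 21.3 TPM and H3.1a (AT1G09200) at 135 ± 9.13 TPM. Their H3.1 copies are near-identical, so the split of reads between them is uncertain. The mitotic cyclin CYCB1;1 (AT4G37490) was lowest at 4.55 ± 1.22 TPM. Clock genes had a median of 21.0 TPM, percentile 99.2 (permutation p 0.0156, adjusted 0.0409). GRP8 (AT4G39260) was at 190.3 ± 8.68 TPM, GRP7 (AT2G21660) at 146 ± 2.65 TPM and ELF4 (AT2G40080) at 3.55 ± 1.06 TPM. Over detected genes alone, cell division (percentile 95.8) and the clock (90.1) lay inside the central 95%.

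Heat shock genes lay inside the central 95% of random lists. The chaperone HSP70 (AT3G12580) was at 10.8 ± 1.06 TPM and HSP18.2 (AT5G59720) at 2.92 ± 0.0281 TPM, and HSP22 (AT4G10250) had no count. With 3 of 9 members detected the list had a median of 1.11 TPM, percentile 14.5 (permutation p 0.289, adjusted 0.354). Touch and wound genes had a median of 20.4 TPM, percentile 96.2 (permutation p 0.0756, adjusted 0.113). Their list lay at 99.1 by the mean (permutation adjusted p 0.0304), 89.1 by CPM, 82.3 over detected genes alone and 75.5 without overlapping genes. TCH4 (AT5G57560) was at 168 ± 2.32 TPM, TCH3 (AT2G41100) at 97.8 ± 2.77 TPM and JAZ10 (AT5G13220) at 1.41 ± 0.168 TPM. Cold, drought and hypoxia genes had a median of 26.8 TPM, percentile 97.6, and their p did not pass adjustment (permutation p 0.049, adjusted 0.0857). Without replicate 3 they lay at 97.3 and by CPM at 86.6, both inside the central 95%. The dehydrins COR47 (AT1G20440) and RAB18 (AT5G66400) were at 170.2 ± 2.39 and 54.1 ± 2.85 TPM, and the fermentation gene PDC1 (AT4G33070) at 1.24 ± 0.18 TPM. Defence and jasmonate genes had a median of 12.2 TPM, percentile 81.3 (permutation p 0.374, adjusted 0.413). LOX2 (AT3G45140), of jasmonate synthesis, was at 51.5 ± 3.14 TPM, the defensin PDF1.2 (AT5G44420) at 29.0 ± 3.48 TPM and PR2 (AT3G57260) at 1.77 ± 0.309 TPM.

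The replicates differed little, and replicate 1 stood slightly apart from the others. Across the 18101 detected genes, which are not independent replicates, Pearson's r of log2 CPM was 0.994 for replicates 1 and 2, 0.995 for 1 and 3 and 0.995 for 2 and 3. A chi-square statistic on the counts, divided by its degrees of freedom, was 3.78, 3.93 and 1.80 for the same pairs, so each pair differed by more than sampling noise. A difference beyond 2-fold was seen in 18, 15 and 7 genes. The common biological coefficient of variation (edgeR) was 4.44%, and 2.93% without replicate 1.

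A small set of genes varied more between the replicates than others of like abundance, and most of them were lowest in replicate 1. Of 18101 genes, 44 were called (edgeR goodness of fit, adjusted p under 0.05), and 1029 had an unadjusted p under 0.05. Replicate 1 was lowest in 41 of the 44 (93.2%), against 35.5% of all detected genes. The plastid share of counts was also lowest in replicate 1. MT3 (AT3G15353), a metallothionein, was at 595 CPM in replicate 1 against 928 and 924 CPM in replicates 2 and 3 (edgeR adjusted p 9.86e-12). The gene with the smallest p, AT3G11620, was at 67.7, 121 and 117 CPM (edgeR adjusted p 1.20e-16), and the plastid gene ATCG00020 at 51.3, 65.0 and 96.8 CPM (edgeR adjusted p 1.20e-16). Without replicate 1 the test called 7 genes, 4 of them among the 44, without replicate 2 it called 27 and without replicate 3 it called 15.

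The other variable genes named by the rule moved by less than 2-fold. AT1G74675 was at 39.6, 63.1 and 69.1 CPM in replicates 1, 2 and 3, and Fes1C (AT5G02150) at 51.4, 85.7 and 83.2 CPM. AT2G18270 was at 23.2, 41.2 and 29.7 CPM, AT3G06070 at 45.7, 68.4 and 73.0 CPM and PAB6 (AT3G16380), a poly(A)-binding protein, at 29.7, 47.6 and 45.6 CPM. IPMI2 (AT2G43100), of leucine and glucosinolate synthesis, was at 76.9, 122 and 104 CPM, and the plastid gene ATCG00220 at 622, 880.4 and 884 CPM. Their edgeR adjusted p-values ran from 1.89e-11 to 7.72e-07. MT3, Fes1C, PAB6, AT3G11620, AT1G74675 and AT2G18270 overlap another gene of the files, as did 29 of the 41 called nuclear genes.

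**Figure D3:**
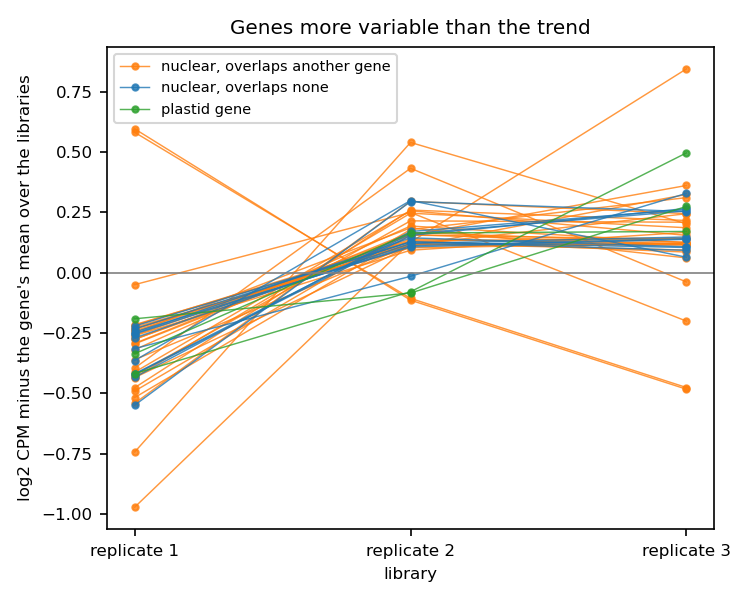
Deviation of each of the 44 genes called more variable than the trend from its own mean over the libraries, in log2 CPM, in replicates 1, 2 and 3, with 1 line per gene coloured by whether it is a plastid gene, a nuclear gene overlapping another or a nuclear gene overlapping none. In 41 of the 44 the lowest value is in replicate 1.

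Functional groups were also compared for how far their members varied between the seedling samples. Cell division genes varied most against random lists of like abundance, at percentile 99.8, and their p did not pass adjustment over the lists (permutation p 0.004, adjusted 0.064). The members with the highest ratio of dispersion to trend were CYCB1;1 (6.502, 4.28 and 4.44 CPM in replicates 1, 2 and 3), H3.1e (98.6, 122 and 119 CPM) and H3.1a (64.1, 76.5 and 72.0 CPM). CYCB1;1 was highest in replicate 1, where H3.1e and H3.1a were lowest. The split of reads between the near-identical H3.1 copies is uncertain, so they may not vary separately. Without replicate 1 the list fell to percentile 81.6 and without replicate 2 to 78.6, and without replicate 3 it lay at 100 (permutation adjusted p 0.0032). With the filter set at 10 counts in every library it lay at 99.93 (permutation adjusted p 0.0272). Other settings gave a permutation adjusted p of 0.227 by total counts, 0.466 by the mean, 0.823 without replicate 1 and 0.969 without replicate 2. No other list lay outside the central 95%, and the others ranged from 6.71 for the Nudix genes to 97.5 for decapping and decay (permutation p 0.0508, adjusted 0.283). Photosystem genes lay at percentile 97.4, at 41.85 by total counts and at 83.5 without replicate 1. Without replicate 3 they lay at 99.8 (permutation adjusted p 0.0352), and without replicate 1 the ribosomal proteins lay at 99.99 (permutation adjusted p 0.0064), both outside the central 95%. Adjusted over the list alone, 1 gene was called in each of 3 lists, NUDT27, PSBY (AT1G67740) and H3.1e, and over all 18101 genes only PSBY of these.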

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

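The fits with a separate spread for each gene, with length, GC or plastid changes removed and without overlapping genes were chosen after seeing the data. Of 286 alternative percentiles of lists and values of COAD minus COAE, 260 kept their side of the central 95% or of p 0.05, and where called their direction. Of 59 alternative counts, 48 lay within 1.5-fold of the main count. The number of detected genes ranged from 18127 to 21717 and the common coefficient of variation under other scalings and filters from 4.44% to 4.52%. No paired analysis was possible because the series has 1 group here. The cause was not tested for any change below unless the setting itself shows it.

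Leaving out each replicate in turn gave a common coefficient of variation of 2.93% (without replicate 1) to 5.10% and 7 to 27 variable genes, with 1 library fewer to show variation. DESeq2 called 84 genes as dispersion outliers, including all 44, and 15 genes were called when overlapping genes were left out, which tests fewer genes. Those 15 were all of the 44 that could be tested there. COAD minus COAE ranged from 0.19 (without replicate 1) to 0.36, and was −0.34 without length correction, where the longer COAE gains. Without that correction 8 Nudix genes were called above NUDT11 and 11 below. Differences that changed sign there were those of NUDT3 (1.4), NUDT7 (0.71), NUDT23 (0.66), NUDT21 (0.10), NUDT2 (0.030) and NUDT8 (0.028), the last 3 with a limma adjusted p of 0.107 to 0.727. NUDT21 lost its call without any 1 of the replicates and NUDT23 without replicate 2 or 3. By median level per gene in place of summed counts, the plastid genes made up 84.9% of the sum of the compartment medians, in place of 0.867% of counts.

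For list levels, percentiles among random lists follow. Over detected genes alone 6 lists lay outside the central 95%, and 5 no longer did, namely decapping and decay (85.3), the clock (90.1), cold and drought (89.9), cell division (95.8) and seed storage (10.1, from 1 gene). The pollen list had no detected member and could not be tested there. By the mean in place of the median the Nudix genes (99.3) and touch genes (99.1) lay outside it and cold and drought (97.4) inside. Cold and drought were at 86.6 by CPM. Without overlapping genes cold and drought (96.7), flower (6.88) and seed storage (3.76) lay inside. Adjusted p-values rose above 0.05 over detected genes alone for cap binding (0.128), the clock (0.338), cell division (0.2185) and seed storage (0.338), by CPM for cell division (0.0903), and without overlapping genes for pollen (0.0672) and seed storage (0.144). They fell below 0.05 by the mean for Nudix genes (0.0245), touch genes (0.0304), flower markers (0.00504) and decapping (0.0018), by CPM for decapping (0.0119), without replicate 1 for flower markers (0.0475) and decapping (0.0485), and without replicate 2 for decapping (0.042). Leaving out replicates in turn gave 96.8 to 97.7 for Nudix genes, 1.1 to 2.53 for flower markers and 97.3 to 97.7 for cold and drought.

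For list spread, DESeq2 size factors and the mean each called 2 lists, and leaving out replicates 1 to 2 lists. Photosystem genes were at 97.75 with DESeq2 size factors, 41.85 by total counts, 99.1 by the mean and 83.5 to 99.8 with a replicate left out. Ribosomal proteins were at 97.85 by the mean and at 32.9 to 99.99 with a replicate left out, the highest without replicate 1 (permutation adjusted p 0.0064). Cell division was at 94.2 by the mean and at 78.6 to 100 with a replicate left out. Of single named genes, 101 of 112 calls of variability held, but each variable gene named by the rule lost its call without 1 of the replicates. Leaving out replicate 1 removed the calls of AT3G11620, MT3, AT1G74675, Fes1C, AT3G06070, IPMI2, PAB6 and ATCG00220 (edgeR adjusted p 0.5459 to 0.9986). AT2G18270 lost its call without replicate 2 (edgeR adjusted p 0.5095) and ATCG00020 without replicate 3 (0.441). Depth limits genes near the floor of 3 counts, such as NUDT24 and the pollen markers.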

Other observations

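Other abundant transcripts, chosen after their values were seen, included genes of chlorophyll synthesis, photorespiration and carbon dioxide supply. Of the 100 genes at 1000 CPM or more, 36 were in the photosystem list, 13 in the Calvin cycle list and 47 in no list. The genes below were picked by eye from the 47, which also hold aquaporins and others, and enrichment was not tested. GUN5 (AT5G13630), a subunit of the magnesium chelatase of chlorophyll synthesis, was at 3349 ± 65.0 CPM (SD, n = 3) and CRD1 (AT3G56940), a cyclase of the same pathway, at 2383 ± 80.9 CPM. Photorespiratory genes included the aminotransferases GGT1 (AT1G23310) at 2596 ± 73.9 CPM and AGT (AT2G13360) at 1963 ± 14.5 CPM. The glycine decarboxylase GLDP1 (AT4G33010) was at 2215 ± 46.8 CPM, SHM1 (AT4G37930) at 2080.2 ± 48.3 CPM and the catalase CAT2 (AT4G35090) at 1849 ± 3.09 CPM. The carbonic anhydrases CA1 (AT3G01500) and CA2 (AT5G14740) were at 2754 ± 66.6 and 1667 ± 32.7 CPM. THI1 (AT5G54770), of thiamine synthesis, was at 3010.3 ± 117 CPM and plastocyanin DRT112 (AT1G20340) at 3321 ± 183 CPM.

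Among the 44 variable genes, also chosen after their values were seen, several encode chloroplast proteins. PSBY of photosystem II was at 1382, 1765 and 1804 CPM in replicates 1, 2 and 3, the ATP synthase subunit ATPD (AT4G09650) at 819, 1079 and 1052 CPM and the ferredoxin FD1 (AT1G10960) at 206, 279 and 271 CPM. OHP2 (AT1G34000), related to antenna proteins, was at 161, 212 and 209 CPM, and the plastid ribosomal protein PSRP3/1 (AT1G68590) at 170, 233 and 227 CPM. Enrichment of such genes was not tested.

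Of the tests that follow, those of gene length, of GC content, of overlapping genes, of plastid carry-over and of near-equal neighbours were chosen after the result was seen. The 44 variable genes, lowest in replicate 1 in 41 cases, had a median length of 921.5 bases against 1804 for all detected genes, and a bias with length or GC content is argued against as the whole cause. After each library's length trend was removed, 90.9% of the 44 remained called. That correction was also small, so most calls were likely to be kept whatever their cause. Its largest shift had a median of 0.030 on the log2 scale, against 0.324 for the largest deviation of the 44. The length trend gave a median of 5.13% of their deviation, and 50.1% at most. The GC trend gave a median of 0.022% of the deviation of the 41 with a GC value (a first GC test, of calls kept after removal, was dropped because the correction moved almost nothing). Of the called nuclear genes 70.7% overlap another gene against 30.6% of the others (Fisher's exact p 1.51e-07, or 24 of 36 and p 1.10e-05 with each of 5 called pairs counted once), so shared reads may contribute to the pattern in some of these 29 genes. They cannot account for the 12 called nuclear genes that overlap no other gene of the files, all lowest in replicate 1 and more than the 2.2 false calls that 5% of 44 allows. A difference between replicate 1 and the others in RNA quality, batch or plant material stays open, and no biological explanation was tested, since the design has 1 group.

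Plastid genes were called variable more often than others, 3 of 74 against 41 of 18027 (Fisher's exact p 0.00077). That p counts the 74 as independent although many moved together. It was also not matched for level. Over all genes, detected or not, plastid genes had a median of 29.0 TPM against 5.12 TPM for nuclear genes, which does not describe the detected genes tested. Carry-over of plastid RNA into poly(A) libraries would likely move all plastid genes alike, and 52 of the 74 were lowest in replicate 1, with medians of −0.09, 0.00 and 0.07 on the log2 scale in replicates 1, 2 and 3 for those not called. After the median change of all 74 in each library was removed, 2 remained called, ATCG00020 and ATCG00220 (edgeR adjusted p 2.98e-10 and 0.00571), and ATCG00490 did not (0.299), so uneven carry-over stays open. A first test with a bound set beforehand, the distance of the called genes from the median of the others, was met at 0.25 against 0.2 and was dropped, because genes picked as variable must lie off that median. ATCG00020 lost its call without replicate 3, ATCG00220 without replicate 1 and with the length trend removed, and no biological explanation was tested.

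Some neighbouring genes had nearly the same counts in every library. Of 8130 adjacent pairs with at least 100 counts, 29 differed by at most 2% in all 3 libraries, against 2 of 7348 pairs 10 genes apart, and 4 were identical, such as RPL27AB (AT1G23290) and AT1G23300 with 2791, 2660 and 3403 counts each. Of the 29 pairs 82.8% overlap in the reference, 22 of them on opposite strands, against 19.8% of other adjacent pairs, which is consistent with reads being counted in full for both genes without regard to strand. A first criterion, that under 10% of other adjacent pairs overlap, was not met, and the comparison with pairs 10 genes apart replaced it after that value was seen. The level of ESB1 (AT2G28670), a root marker with 228, 256 and 303 counts beside 229, 255 and 298 for AT2G28671, may thus belong to either gene, and no biological explanation was tested.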
